A study of Mus musculus with 6 samples.

How the data were processed

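Total RNA from 6 samples of mouse HoxB8 neutrophil progenitors was profiled on Affymetrix Mouse Clariom S arrays after 1 day of differentiation, 3 arrays from cells that expressed wild-type C/EBPα (WT) and 3 from cells that expressed the K313 form (K313), per the labels. The labels do not say whether the replicates of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The labels name no scan date, slide or other batch, and none could be tested.

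The deposited values are log2 expression values. Per the submitters' processing notes they were made with RMA (background correction, normalization across arrays and summarization per probe set) and the Transcriptome Analysis Console; no version of either is given in the sources used here. The deposited log2 values have 2 decimals and run from 2.21 to 18.59, and the array medians lie between 5.01 and 5.13. RMA brings the arrays to a common distribution, so a change in total RNA per cell does not appear in these values, and it compresses the folds of probe sets near the low end. No detection calls were used here, so a level near 3 to 5 cannot be told from background and a fold from such a level is a compressed estimate. Of 119 called genes named by the rule below or marked as chosen afterwards, 27 had a mean of at most 5 in at least 1 group: 3 in both, 14 in WT alone and 10 in K313 alone. Arrays have no read depth, and their number, 3 per group, limits the precision: the median standard error of a log2 difference was 0.18.

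The table holds 22206 probe sets and no column of other samples. Genes were named from the platform annotation: 19572 probe sets have 1 gene symbol, 0 have several and 2634 have none. All 19572 gene identifiers were found in the RefSeq gene table of assembly GRCm38.p6. The build of the array design is not given in the sources used here, so no coordinates are printed; that table served only for symbols and for which genes neighbour each other, and chromosomes were read from the probe set names. Probe sets without a symbol stayed in the tests and are not named. No control probe sets were in the table. 55 symbols have more than 1 probe set; each probe set was tested on its own.

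The test was fixed before the data were examined: limma 3.58.1 (R 4.3.3), lmFit with the group as the only term and eBayes with its default prior, two-sided, on all 22206 probe sets, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p given for a gene comes from this limma fit. Changes are K313 minus WT on the log2 scale, and errors of a change are standard errors of the fit. A second count added a change of at least 1.5-fold. The test was checked on simulated data for this comparison, with 22206 probe sets and 50 changed probe sets at each size. Of these, 6% were recovered at a log2 change of 0.5, 92% at 1, 100% at 2 and 100% at 3, and 12 of 161 calls were false. The simulated noise was independent between probe sets and used the variances of the fit after shrinkage. Fewer probe sets changed in it than were called in the data. The rates therefore describe the simulation and may differ for the data.

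34 gene lists with 966 distinct genes, of which 865 were measured, were also fixed before the data were examined. They cover the C/EBP family and its targets, granules and maturation, other blood cell types, progenitors, transcription factors, receptors, the cell cycle, translation, stress responses, inflammation and metabolism. Each was tested against the other probe sets with camera at its preset correlation of 0.01, adjusted over the 34 lists. The alternatives were camera with a correlation estimated per list, and fry, which tests whether a list's own genes move, on balance, 1 way. Member counts use the adjusted p over all probe sets, with the count "adjusted over the list alone" beside it. 4 list symbols were updated to the symbols of the array (Ero1a, Ero1b, Atp5pb and Zfp598); this was decided after a first look at the list tests, and the result without it is given with the list it changes.

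Genes named in the text follow a rule fixed beforehand: the 12 largest rises and 12 largest falls among probe sets with 1 symbol, past the threshold and with no overlap between the 3 K313 and the 3 WT values, leaving out unnamed gene models and olfactory and vomeronasal receptors; all C/EBP family members; and for each list up to 4 members with the smallest p. A gene outside the rule is marked as chosen after its values were seen, apart from the 6 X-linked escape genes, which were set before theirs were seen. Prtn3, also outside the rule, is named only as a neighbour of Elane. It was picked after the calls were seen and is not among the 119 called genes counted above.

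Alternatives set beforehand were quantile normalization of the deposited values, a shift of each array to a common median, removal of the lowest 30% of probe sets by mean, an intensity trend with a robust prior, array quality weights, ordinary variance per gene without shrinkage, the replicate number as a block, only probe sets with 1 symbol, unadjusted p under 0.05 with at least 2-fold change, and each array left out in turn. Chosen after seeing the data were a fit without WT replicate 3 and without the 219 Y chromosome probe sets, and list tests without the updated symbols.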

Results

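Gene expression was measured in mouse HoxB8 neutrophil progenitors, progenitors held in an immature state by the transcription factor Hoxb8, after 1 day in differentiation medium. One group expressed wild-type C/EBPα (WT, 3 arrays) and the other the leukaemia-associated K313 form (K313, 3 arrays). C/EBPα is the transcription factor that drives granulocyte formation, and the series asks how the K313 form alters its activity. Across the 22206 probe sets, arrays of the WT group correlated with each other at 0.994 to 0.995 (Pearson's r over probe sets, which are not independent), arrays of the K313 group at 0.995 to 0.996, and arrays of different groups at 0.983 to 0.989. WT replicate 3 had the highest correlations with K313, 0.987 to 0.989, against 0.983 to 0.986 for the other WT arrays.

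The Cebpa transcript itself was not detectably different between the groups. Its log2 level was 14.53, 14.85 and 14.35 in the WT arrays and 13.85, 13.90 and 14.45 in the K313 arrays, a difference of -0.51 ± 0.21 (SE, n = 3 per group; limma adjusted p = 0.212; 95% interval -0.96 to -0.06 before adjustment). The labels do not state whether this probe set sees the introduced forms, so it does not check them. Among the other family members, Cebpd differed by 0.38 ± 0.16 (adjusted p = 0.235), Cebpb by 0.12 ± 0.15 (0.782), Cebpe by -0.04 ± 0.16 (0.939) and Cebpg by 0.00 ± 0.15. Ddit3, the C/EBP family member induced by endoplasmic reticulum and integrated stress, was the 1 member that fell: its first probe set changed by -0.99 ± 0.24 (adjusted p = 0.0292), while the second, at -0.60 ± 0.18, stayed short of the threshold (0.0729). The Ddit3 call was lost with quantile normalization (0.0527), with ordinary variance (0.289), without WT replicate 1 (0.0853), without WT replicate 2 (0.0941), without K313 replicate 1 (0.0707) and without K313 replicate 2 (0.0517). As a list, the family of 7 probe sets did not differ from other genes (camera adjusted p = 0.282), with 0 higher and 2 lower when adjusted over the list alone.

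Expression differed widely between the groups. Of 22206 probe sets, 1720 (7.75%) passed the threshold, 838 higher and 882 lower in K313, and 1708 of them changed at least 1.5-fold. At least 10-fold changes were reached by 82 probe sets that rose and 34 that fell. The groups did not overlap in 4872 probe sets (21.9%), where chance gives 10%. The largest rise was in Chil3, a chitinase-like protein of myeloid granules, from a log2 level of 5.21 ± 3.10 (SD, n = 3) in WT to 13.82 ± 0.92 in K313, a change of 8.62 ± 1.14 (SE; adjusted p = 0.000544). Next came the Y-linked gene Eif2s3y (7.88 ± 0.83), the microsomal glutathione transferase Mgst1 (7.63 ± 0.75), the Y-linked gene Uty (7.23 ± 0.65), the neutrophil collagenase Mmp8 (6.99 ± 0.43) and grancalcin, Gca, a calcium-binding protein of neutrophils (6.87 ± 0.52). Socs2, an inhibitor of cytokine signalling, rose by 6.59 ± 0.54, the galactosyltransferase B4galt6 by 6.53 ± 0.60, the thyroid hormone deiodinase Dio2 by 6.36 ± 0.46, the acyltransferase Glyat by 6.31 ± 0.64, the proteasome subunit Psma8 by 6.07 ± 0.46 and the calcium-binding protein Kcnip3 by 5.91 ± 0.39. Adjusted p-values of these 12 rises lay between 2.45e-06 (Mmp8) and 0.000544 (Chil3). Eif2s3y, Uty and Psma8 rose from WT means of at most 5, near background, so their sizes are compressed estimates.

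The largest fall was in Nrg1, the growth factor neuregulin, from 12.90 ± 0.34 (SD, n = 3) to 5.82 ± 0.26, a change of -7.08 ± 0.21 (SE; adjusted p = 2.55e-08). It was followed by the cadherin Cdh17 (-5.55 ± 0.23), the succinate receptor Sucnr1 (-5.40 ± 0.34) and the zinc finger genes Zfp846 (-4.89 ± 0.15) and Zfp711 (-4.80 ± 0.42). Hoxb8, whose product gives these progenitors their name, fell from 12.98 ± 0.52 to 8.34 ± 0.25 (SD, n = 3), a change of -4.64 ± 0.25 (SE; adjusted p = 1.15e-06). Whether its probe set sees the introduced copy is not stated. Since Hoxb8 holds these progenitors immature, its lower level is a further difference between the groups. Its part in the other changes was not tested and cannot be told apart from that of the C/EBPα form. Renbp changed by -4.61 ± 0.29, the oxysterol receptor Gpr183 by -4.60 ± 0.22, the growth factor Fgf3 by -4.56 ± 0.18 and the prostaglandin D synthase Hpgds by -4.50 ± 0.19. Mzb1, a protein of antibody-secreting B lineage cells, changed by -4.45 ± 0.22 and granzyme B, Gzmb, by -4.33 ± 0.39. Sucnr1, Zfp846, Renbp, Gpr183, Hpgds, Mzb1 and Gzmb fell to K313 means of at most 5, near background, so their sizes and order are compressed estimates.

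**Figure D1:**
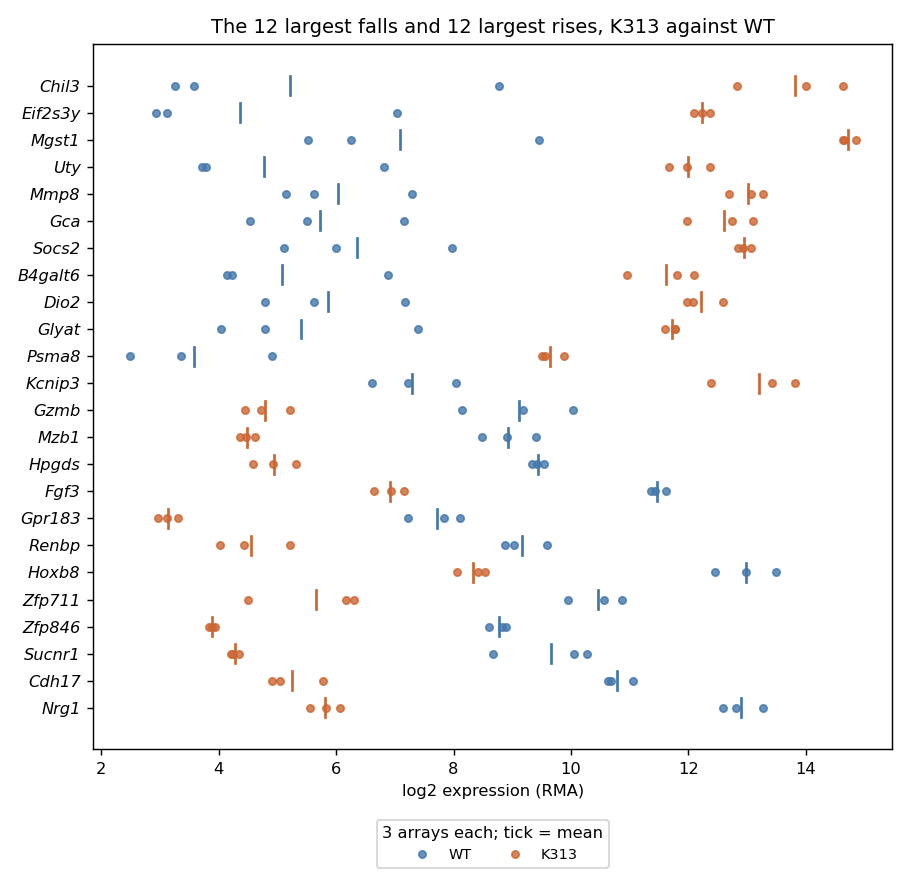
Log2 expression (RMA, horizontal axis) of the 12 largest rises and 12 largest falls in K313 against WT; points are single arrays, 3 per group, and vertical ticks are group means. Chil3 stands at a mean of 5.21 in WT and 13.82 in K313 and Nrg1 at 12.90 and 5.82, and in the 12 genes that rose the right-most WT point is WT replicate 3.

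In the genes that rose most, WT replicate 3 lay apart from the other WT arrays. Chil3 read 3.58 and 3.26 in WT replicates 1 and 2 and 8.78 in replicate 3, and Mgst1 read 5.52, 6.26 and 9.46. The Y-linked genes behaved alike: Eif2s3y read 3.11, 2.93 and 7.03 in the WT arrays against 12.37, 12.09 and 12.24 in K313, Uty 3.72, 3.78 and 6.81 against 12.37, 11.67 and 11.97, and Kdm5d, chosen after its values were seen, 3.10, 3.37 and 4.31 against 8.81, 8.17 and 7.70. The groups therefore differed in their Y-linked transcripts besides the C/EBPα form. Without WT replicate 3 the changes were larger by over 1.5-fold in 11 of the 12 largest rises. They were 10.40 for Chil3, 9.21 for Eif2s3y, 8.82 for Mgst1, 8.25 for Uty, 7.63 for Mmp8, 7.58 for Gca, 7.40 for Socs2, 7.43 for B4galt6, 7.02 for Dio2, 7.31 for Glyat and 6.74 for Psma8. Kcnip3 moved less, to 6.29. Leaving out WT replicate 1 gave smaller changes, 7.80 for Chil3, 7.25 for Eif2s3y, 6.85 for Mgst1, 6.28 for Gca and 5.96 for Socs2, and leaving out WT replicate 2 gave 7.64 for Chil3, 7.16 for Eif2s3y and 5.62 for Glyat. A fit without WT replicate 3 and without Y chromosome probe sets, chosen after seeing the data, gave 1438 probe sets, 757 higher and 681 lower. With an intensity trend and robust prior Chil3 missed the threshold (adjusted p = 0.0777), and with ordinary variance per gene 496 probe sets passed in place of 1720.

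**Figure D2:**
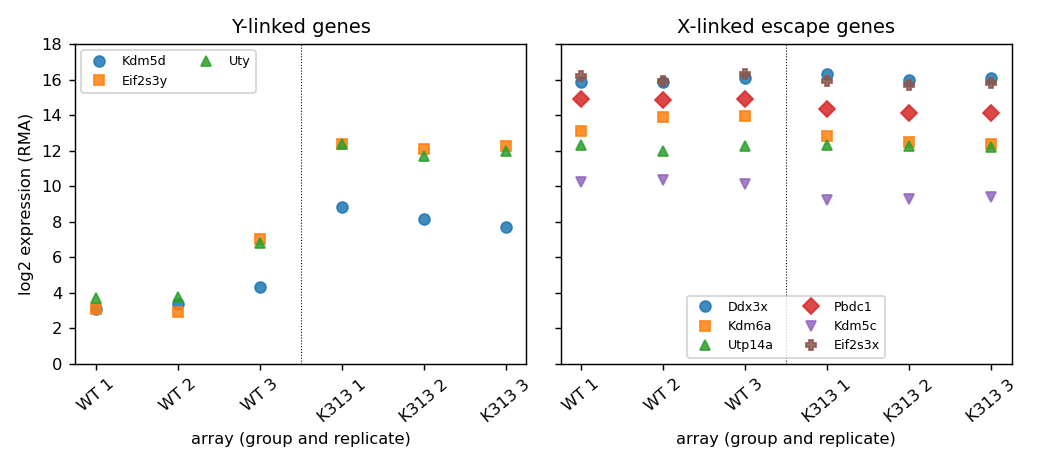
Log2 expression (RMA, vertical axis) in each of the 6 arrays for 3 Y-linked genes (left) and 6 X-linked genes that escape X inactivation (right); each point is 1 array and the dotted line parts WT from K313. Eif2s3y reads 2.93 to 3.11 in WT replicates 1 and 2, 7.03 in WT replicate 3 and 12.09 to 12.37 in K313.

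Across the 34 gene lists, 16 differed from other genes with camera, 8 higher and 8 lower in K313. Some lists share genes, such as Elane and Gata1, so the list calls are not independent of each other. With a correlation estimated per list, 0 lists passed (smallest adjusted p = 0.214; 7 lists had an unadjusted p under 0.05), and 17 passed with fry, which tests a list on its own, 14 of them among the 16. Fry lost ribosome biogenesis (adjusted p = 0.201) and glycolysis and hypoxia (0.131) and gained the NF-kB (0.0335), fatty acid (0.0260) and growth factor receptor (0.0329) lists. All 16 passed again without WT replicate 3. The loss of lists with an estimated correlation need not mean a high correlation within them. The eosinophil, transcription factor and interferon lists were lost at estimated correlations of -0.014, -0.024 and 0.0086, under the preset of 0.01.

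Granule genes rose. Of 20 primary granule genes, which encode the proteases and enzymes that promyelocytes store first, 11 rose and 1 fell (11 and 1 adjusted over the list alone; camera adjusted p = 5.82e-06, and adjusted p = 0.214 with an estimated correlation). Clec12a, a myeloid inhibitory receptor placed on that list, rose by 3.68 ± 0.26, neutrophil elastase, Elane, by 3.29 ± 0.28, cathepsin G, Ctsg, by 1.75 ± 0.16 and the glutathione transferase Gstm1 by 1.62 ± 0.16 (limma adjusted p between 5.42e-06 and 5.38e-05). Myeloperoxidase, Mpo, chosen after its values were seen, was at the top of the measured range in both groups, 18.41 in WT and 18.42 in K313, where a change would be hard to see. Of 24 secondary and tertiary granule genes, 8 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 3.51e-05, and adjusted p = 0.214 with an estimated correlation). They include Mmp8, haptoglobin, Hp (2.69 ± 0.18), lipocalin 2, Lcn2 (2.09 ± 0.23), and annexin A1, Anxa1 (1.48 ± 0.17). The secondary granule proteins lactoferrin, Ltf, and cathelicidin, Camp, both chosen after their values were seen, stayed near the low end in both groups (3.22 and 3.24 for Ltf, 3.38 and 3.38 for Camp). Without WT replicate 3, 10 primary and 7 secondary and tertiary granule genes rose. The 1 fall among the secondary and tertiary granule genes was lost without WT replicate 1, WT replicate 2, K313 replicate 2 or K313 replicate 3.

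Late neutrophil markers went both ways, with 6 higher, 4 lower and 14 short of the threshold (7 and 5 adjusted over the list alone; camera adjusted p = 0.323). The chemokine receptor Cxcr2, which guides mature neutrophils out of the marrow, fell by 2.08 ± 0.15 on the log2 scale and the interleukin 1 decoy receptor Il1r2 fell by 1.52 ± 0.18, while the chemokine receptor Ccr1 rose by 1.79 ± 0.17 and the lectin Clec4e by 1.73 ± 0.18. The calgranulin genes S100a8 (4.0 ± 0.63) and S100a9 (2.68 ± 0.55), chosen after their values were seen, also rose. Their changes were 4.80 and 3.37 without K313 replicate 1 and 3.19 and 2.04 without K313 replicate 3. Both missed the threshold with an intensity trend and robust prior (adjusted p = 0.0583 and 0.0641). S100a8 rose from a WT mean near background (4.97), and Il1r2 fell to a K313 mean near background (4.72). Of 6 NADPH oxidase genes, Cybb alone rose (1.20 ± 0.32, adjusted p = 0.0450). It rose from levels near background and in 2 of the 6 fits that leave out an array, and missed the threshold with quantile normalization (limma adjusted p = 0.0510). Ncf1 differed by -0.24 ± 0.16, Rac2 by -0.16 ± 0.15 and Ncf4 by 0.11 ± 0.17 (list camera adjusted p = 0.737).

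Monocyte and macrophage genes also rose, 11 of 27 against 3 that fell (13 and 3 adjusted over the list alone; camera adjusted p = 0.000119, and adjusted p = 0.214 with an estimated correlation). The chemokines Ccl9 and Ccl6 rose by 2.58 ± 0.16 and 4.57 ± 0.34, the lipopolysaccharide co-receptor Cd14 by 4.45 ± 0.32 and the membrane protein Ms4a6c by 4.32 ± 0.32. Without K313 replicate 2, 7 rose and 2 fell, and without WT replicate 3, 8 rose and 2 fell.

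Genes of basophils and mast cells fell. Of 19 measured, 10 fell and 1 rose (12 and 1 adjusted over the list alone; camera adjusted p = 4.94e-08, and adjusted p = 0.214 with an estimated correlation). The inhibitory receptor family member Cd200r3 fell by 4.03 ± 0.23 on the log2 scale, the transcription factor Gata1 fell by 3.69 ± 0.24 and the membrane protein Ifitm1 fell by 1.59 ± 0.15. Prss34, the basophil protease mMCP-11, went the other way and rose by 3.98 ± 0.21 (adjusted p = 1.16e-06), with all 3 K313 arrays above all 3 WT arrays. Of 9 eosinophil genes, 4 fell and 1 rose (4 and 1 adjusted over the list alone; camera adjusted p = 0.0162, and adjusted p = 0.214 with an estimated correlation). The interleukin 5 receptor Il5ra fell by 2.88 ± 0.21, the granule protein Prg2 fell by 1.77 ± 0.29, Siglecf fell by 0.92 ± 0.18, and the lipoxygenase Alox15 rose by 1.67 ± 0.28. Without K313 replicate 2 the falls numbered 2, and Siglecf missed the threshold (adjusted p = 0.0538).

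Of 17 erythroid and megakaryocyte genes, 7 fell and 1 rose (8 and 2 adjusted over the list alone; camera adjusted p = 0.000862, and adjusted p = 0.346 with an estimated correlation). Besides Gata1, the platelet glycoprotein Gp9 fell by 2.68 ± 0.18, carbonic anhydrase 2, Car2, fell by 1.69 ± 0.25, and the Gata1 cofactor Zfpm1 fell by 1.34 ± 0.22. The count of rises ranged from 0 to 3 when arrays were left out. Stem and progenitor genes fell in 7 of 22 and rose in 2 (11 and 2 adjusted over the list alone; camera adjusted p = 0.000119, and adjusted p = 0.214 with an estimated correlation). The falls include Hoxb8, for which it is not stated whether the probe set sees the introduced copy. The niche factor Angpt1 fell by 2.71 ± 0.16 and the transcription factor Ikzf2 fell by 1.56 ± 0.17, while the transcription cofactor Lmo2 rose by 2.17 ± 0.20. Of 19 lymphocyte genes, 5 fell and 1 rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.0313, and adjusted p = 0.452 with an estimated correlation). The B cell receptor components Cd79b and Cd79a fell by 3.93 ± 0.24 and fell by 1.40 ± 0.17, the recombinase subunit Rag2 fell by 1.64 ± 0.17 and the T cell receptor component Cd3g fell by 1.49 ± 0.24, the last from 4.75 to 3.26, levels near background in both groups. That list missed the threshold without WT replicate 2 (camera adjusted p = 0.0541) and without K313 replicate 3 (0.147). Cd79a fell to a K313 mean near background (4.9). Dendritic cell genes did not differ as a list (1 higher and 3 lower among 20 probe sets, 3 and 3 adjusted over the list alone; camera adjusted p = 0.460). Single members passed: the antigen loading gene H2-DMb1 fell by 2.10 ± 0.18, Id2 fell by 3.75 ± 0.39, the integrin Itgax fell by 0.80 ± 0.16 at levels near background in both groups (4.97 and 4.17), and H2-DMa rose by 1.14 ± 0.22 from a level near background (4.62).

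**Figure D3:**
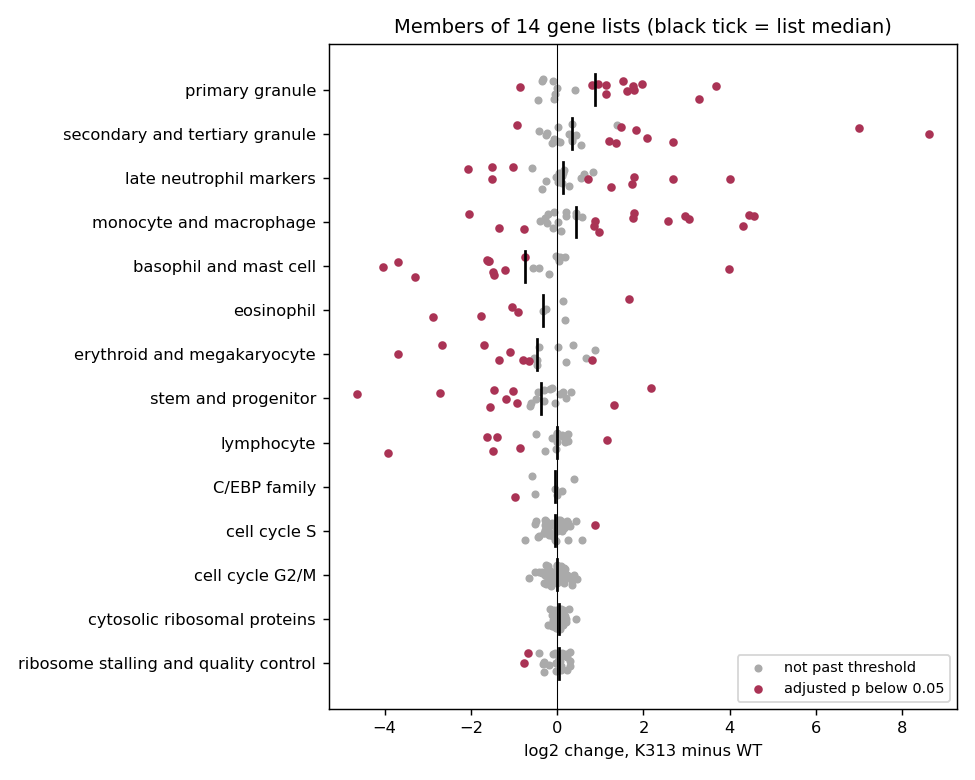
Log2 change, K313 minus WT (horizontal axis), of each member probe set of 14 gene lists; red points passed an adjusted p of 0.05, grey points did not, and black ticks are list medians (vertical scatter is for legibility). The ticks stand at 0.87 for primary granule genes and at -0.74 for basophil and mast cell genes, and at 0.03 for cytosolic ribosomal proteins.

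Of 20 genes known to be activated by C/EBPα in granulocyte precursors, 7 rose and 1 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.00735, and adjusted p = 0.318 with an estimated correlation). The median change was 0.01 and the mean 0.66. The members with the smallest p were Elane, Hp, the interleukin 6 receptor Il6ra (2.57 ± 0.21) and the transcription factor Klf5 (2.08 ± 0.20, from a level near background, 3.67). Elane and Hp also stand on the granule lists, so the call of this list is not separate from theirs. The falls numbered 0 without K313 replicate 2 and 3 without K313 replicate 3. Of 12 genes known to be repressed by C/EBPα, 2 fell and 0 rose with limma (5 and 0 adjusted over the list alone; at an unadjusted p under 0.05, 6 lower and 0 higher; camera adjusted p = 0.0162, and adjusted p = 0.292 with an estimated correlation). These were Gata2 (-1.47 ± 0.19) and Sox4 (-1.18 ± 0.22), both transcription factors of progenitors. Meis1 (-0.62 ± 0.17, adjusted p = 0.0555) and Ebf1 (-0.49 ± 0.18, 0.148) did not pass. Meis1 passed with a common median (0.0350), a low-signal filter (0.0474), an intensity trend (0.04995), array weights (0.0453) and 1-symbol probe sets (0.04995). Among 29 granulocyte and lineage transcription factors, 4 fell and 1 rose (6 and 2 adjusted over the list alone; camera adjusted p = 0.0149, and adjusted p = 0.214 with an estimated correlation). Id2, an inhibitor of DNA binding, fell by 3.75 ± 0.39 and Runx3 fell by 2.01 ± 0.26. Gfi1b, a transcriptional repressor that acts in erythroid and megakaryocyte cells, fell by 1.74 ± 0.25, whereas Klf5 rose. Growth factor and cytokine receptors went both ways, with 6 of 29 higher and 7 lower (6 and 9 adjusted over the list alone; camera adjusted p = 0.116): Il6ra and Ccr1 rose, and Il5ra and Cxcr2 fell. Without K313 replicate 2 the lower receptors numbered 4.

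The series title concerns translation and ribosome stalling, and genes of the translation machinery showed few changes in RNA. Of 55 cytosolic ribosomal protein genes, 0 passed with limma (1 at an unadjusted p under 0.05, 0 with ordinary variance, 0 adjusted over the list alone), with a median change of 0.03 (camera adjusted p = 0.590). The smallest p-values were those of Rps15 (0.43 ± 0.17, adjusted p = 0.197), Rpl9 (0.28 ± 0.17), Rplp0 (0.20 ± 0.15) and Rps25 (-0.21 ± 0.17). Of 38 translation initiation and elongation factors, 0 passed with limma (1 at an unadjusted p under 0.05, 0 with ordinary variance, 0 adjusted over the list alone; camera adjusted p = 0.153, and 0.0478 with quantile normalization). Eif4h differed by 0.55 ± 0.19 (adjusted p = 0.134). Of 26 genes of ribosome stalling and quality control, 2 fell and 0 rose with limma (2 and 0 adjusted over the list alone; at an unadjusted p under 0.05, 3 lower and 0 higher; 0 with ordinary variance; camera adjusted p = 0.712). Trip4, a subunit of the complex that splits collided ribosomes, fell by 0.69 ± 0.16 at levels near background in both groups and the stalling-sensing kinase Map3k20 fell by 0.77 ± 0.19 (adjusted p = 0.0257 and 0.0289). Both calls were lost without WT replicate 3, K313 replicate 2 or K313 replicate 3, Trip4 also without WT replicate 2 or K313 replicate 1 and Map3k20 without WT replicate 1. The collision sensor Zfp598 (-0.43 ± 0.16, adjusted p = 0.184) and the exonuclease Xrn1 (-0.32 ± 0.18) did not pass.

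MYC-linked ribosome biogenesis genes lay slightly higher as a list (median change 0.12; camera adjusted p = 0.0313, and adjusted p = 0.595 with an estimated correlation), yet 0 of 44 passed with limma (7 at an unadjusted p under 0.05, 0 with ordinary variance, 0 adjusted over the list alone). Cad differed by 0.55 ± 0.20, Mrto4 by 0.44 ± 0.17, Polr1b by 0.45 ± 0.17 and Nolc1 by 0.46 ± 0.18. The list missed the threshold without WT replicate 2 (0.209) and without K313 replicate 2 (0.215). Unfolded protein response genes rose in 3 of 25, with 0 lower with limma (4 and 0 adjusted over the list alone; 1 lower at an unadjusted p under 0.05; camera adjusted p = 0.0216, and adjusted p = 0.452 with an estimated correlation). The endoplasmic reticulum oxidase Ero1b rose by 2.72 ± 0.23, the degradation factor Edem1 by 0.80 ± 0.15 and the stress sensor Ern1 by 0.72 ± 0.17, while Ero1a, at 0.56 ± 0.16, missed the threshold (adjusted p = 0.0565). Ero1a passed with quantile normalization (0.0450), a low-signal filter (0.04997), an intensity trend (0.0142) and array weights (0.0450). This list call rests on the updated symbols, which brought in Ero1a and Ero1b: without them camera's adjusted p was 0.115. It was also lost without WT replicate 2 (0.0860) and without K313 replicate 1 (0.0515), and Ern1 passed in 1 of the 6 fits that leave out an array. Among 36 probe sets of the integrated stress response, 1 rose and 3 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.0585, in the direction higher). Ddit4 (-0.94 ± 0.23), Ddit3 and the glycine transporter Slc6a9 (-0.96 ± 0.24) fell and asparagine synthetase, Asns, rose (0.81 ± 0.21). Each of these calls was lost in at least 4 of the 6 fits that leave out an array. Ddit4 also missed the threshold with the replicate block (limma adjusted p = 0.0529), Asns with a common median (0.0638) and Slc6a9 with array weights (0.0544). The list passed with quantile normalization (0.0352), without WT replicate 1 (0.0139) and without K313 replicate 1 (0.0152).

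Cell cycle genes changed little. Of 46 S phase genes, 1 rose, the cyclin Ccne1 (0.87 ± 0.17, adjusted p = 0.00920; 1 adjusted over the list alone; camera adjusted p = 0.460). Dscc1 differed by -0.75 ± 0.22 (adjusted p = 0.0633; 0.0479 with a common median and 0.0400 without WT replicate 2), Orc1 by -0.51 ± 0.16 and Cdc45 by 0.58 ± 0.20. Of 54 G2/M genes, 0 passed with limma (6 at an unadjusted p under 0.05, 2 higher and 4 lower; 0 with ordinary variance, 0 adjusted over the list alone; camera adjusted p = 0.460). Kif23 had the smallest p (-0.52 ± 0.15, adjusted p = 0.0658), and passed with a common median (0.0434) and an intensity trend (0.0407). Of 27 p53 targets, 5 fell and 0 rose with limma (5 and 0 adjusted over the list alone; at an unadjusted p under 0.05, 9 lower and 0 higher; camera adjusted p = 0.0117, and adjusted p = 0.270 with an estimated correlation). The membrane protein Perp fell by 1.69 ± 0.17, Trp53inp1 fell by 1.99 ± 0.22, the cell cycle inhibitor Cdkn1a fell by 1.30 ± 0.21 and the kinase Plk3 fell by 0.90 ± 0.16. Apoptosis regulators went both ways (3 higher and 2 lower of 23, 4 and 2 adjusted over the list alone; camera adjusted p = 0.590). The death ligand Tnfsf10 rose by 1.70 ± 0.21 and the survival gene Bcl2a1d by 1.03 ± 0.15, the latter from a level near background (4.26 to 5.28). The pro-apoptotic Bcl2l11 (-1.03 ± 0.16) and Casp1 (-0.93 ± 0.17) fell.

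In the NF-kB and inflammatory list 6 of 30 genes fell and 2 rose (6 and 2 adjusted over the list alone), which did not set the list apart (camera adjusted p = 0.120). The cytokine Il6 fell by 2.29 ± 0.17, the chemokine Ccl3 fell by 3.32 ± 0.29 and the growth factor Csf1 fell by 1.72 ± 0.21, while the interleukin 1 antagonist Il1rn rose by 1.58 ± 0.21 from a level near background (3.58). Of 30 probe sets of AP-1 and immediate early genes, 5 fell and 0 rose with limma (6 and 1 adjusted over the list alone; 4 higher at an unadjusted p under 0.05; camera adjusted p = 0.112). The phosphatase genes Dusp5 and Dusp1 fell by 1.34 ± 0.17 and fell by 1.95 ± 0.31, Jund fell by 1.19 ± 0.18 and Zfp36 fell by 0.78 ± 0.18, the last in 2 of the 6 fits that leave out an array. Falls numbered 3 without K313 replicate 2 and 3 without K313 replicate 3. Interferon-stimulated genes rose in 5 of 35 and fell in 1 (6 and 1 adjusted over the list alone; camera adjusted p = 0.0313, and adjusted p = 0.270 with an estimated correlation). The RNA sensor Ifih1 rose by 3.06 ± 0.33, Gbp3 by 1.76 ± 0.30 (from a level near background, 4.19) and Ifi35 by 0.74 ± 0.15. The deconjugase Usp18 fell by 0.74 ± 0.15, to a level near background (4.55). The list missed the threshold without WT replicate 2 (0.135) and without K313 replicate 1 (0.0540). Rises numbered 3 without K313 replicate 1 and 3 without K313 replicate 3, and Ifi35 missed it without K313 replicate 2 (0.0628).

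Among metabolic lists, glycolysis and hypoxia genes rose in 3 of 29 and fell in 1 (4 and 1 adjusted over the list alone; camera adjusted p = 0.0278, and adjusted p = 0.558 with an estimated correlation). The 3 rises were in phosphofructokinase genes or their regulator, Pfkp (2.33 ± 0.31), Pfkfb3 (1.15 ± 0.17) and Pfkl (1.01 ± 0.19), and the glucose transporter Slc2a3 fell by 1.55 ± 0.17. The list missed the threshold without WT replicate 2 (0.180) and without K313 replicate 3 (0.0509). Of 65 oxidative phosphorylation genes, 0 passed with limma (6 at an unadjusted p under 0.05, 1 with ordinary variance, 0 adjusted over the list alone; camera adjusted p = 0.130). Cyc1 differed by 0.54 ± 0.17 (adjusted p = 0.0809). That list passed with quantile normalization (0.0353), without WT replicate 1 (0.0181) and without K313 replicate 1 (0.00679). Fatty acid and lipid droplet genes rose in 3 of 31 and fell in 1 (5 and 1 adjusted over the list alone; camera adjusted p = 0.578), led by the fatty acid binding protein Fabp5 (2.56 ± 0.18) and the triglyceride synthase Dgat2 (2.35 ± 0.27). Scd1 (1.00 ± 0.25) and Elovl6 (-0.79 ± 0.20) passed in 2 of the 6 fits that leave out an array. Scd1 also missed the threshold with the replicate block (limma adjusted p = 0.0519). In cholesterol synthesis Hmgcs1 rose by 1.04 ± 0.20 and Fdft1 fell by 0.80 ± 0.17 among 20 genes (2 and 3 adjusted over the list alone; camera adjusted p = 0.676), the latter in 3 of the 6 such fits. In the heat shock list Bag3 rose by 1.41 ± 0.26 and Dnajb4 fell by 0.88 ± 0.18 among 18 genes (1 and 1 adjusted over the list alone; camera adjusted p = 0.574), and Dnajb4 missed the threshold without K313 replicate 3 (0.0511).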

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

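The fit without WT replicate 3 and Y chromosome probe sets and the list tests without updated symbols were chosen after seeing the data. The main fit has 3 arrays per group, and its count of probe sets stayed within 1.5 times of 1720 under quantile normalization (1743), a common median (1791, with 727 higher and 1064 lower), a low-signal filter (1788), an intensity trend (1771), array weights (1776), 1-symbol probe sets (1647) and without WT replicate 3 and Y chromosome probe sets (1438). With ordinary variance per gene it fell to 496 (247 higher, 249 lower), and to 454 with 1.5-fold (232 higher, 222 lower). That fit does without the 6.83 prior degrees of freedom that eBayes adds to each gene, which lowers its power. Whether anything else adds to the drop was not tested. In that fit 62 of 119 called genes named by the rule or chosen afterwards missed the threshold. Chil3, Eif2s3y, Mgst1, Uty, Gca, Socs2, B4galt6, Glyat, Gzmb and Zfp711 were among them. The rule of unadjusted p under 0.05 with 2-fold change gave 1011 (536 higher, 475 lower), its size limit leaving out smaller changes. Leaving out 1 array gave 1228 to 1465 probe sets, with 625 to 760 higher and 575 (without K313 replicate 2) to 776 lower. The values gave no sign that the replicate numbers pair the samples. Same-numbered arrays had correlations of deviations of -0.061, 0.029 and -0.062, and WT replicate 3 correlated best with K313 replicate 1 (0.138). With 3 arrays per group these correlations cannot exclude a pairing, and the labels do not state one. With the replicate block 1546 probe sets passed, 777 higher and 769 lower, and 16 lists.

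The number of C/EBP family calls was 0 with quantile normalization, 0 with ordinary variance, 2 with a common median and 0 to 1 with 1 array left out; Ddit3 lies near the threshold. The number of lists past the threshold was 16. It was 19 with quantile normalization, 15 without updated symbols and 17 with fry (14 of them among the 16). With 1 array left out it was 11 (without WT replicate 2) to 18 (without WT replicate 1). With an estimated correlation it was 0, for which the cause was not tested. The eosinophil, transcription factor and interferon lists had estimated correlations of -0.014, -0.024 and 0.0086, under the preset of 0.01. Their unadjusted camera p still rose from 0.00524 to 0.0440, from 0.00395 to 0.0311 and from 0.0147 to 0.0678. A high correlation within these lists therefore does not account for their loss. Signs turned only where the change was near 0, and the cause was not tested. Ltf (0.01) turned to -0.016 with quantile normalization and -0.063 with a common median, and ran from -0.063 (without WT replicate 2) to 0.072 with 1 array left out. Mpo (0.00) turned to -0.073 with a common median and -0.023 without WT replicate 3 and Y chromosome probe sets, and ran from -0.023 (without WT replicate 3) to 0.052. Cebpe (-0.04) ran from -0.15 to 0.028 (without K313 replicate 2). The lists that turned had these camera adjusted p. Ribosome stalling had 0.930 with quantile normalization, 0.809 without WT replicate 3 and Y chromosome probe sets, and 0.273 to 0.816 with 1 array left out. G2/M genes had 0.991 without WT replicate 3 and Y chromosome probe sets and 0.209 to 1.00 with 1 array left out, ribosomal proteins 0.942 and 0.124 to 0.933. Apoptosis regulators ran from 0.419 to 0.955 and cholesterol synthesis from 0.502 to 0.944 with 1 array left out. The median change of all probe sets was 0.02 as deposited, -0.01 with quantile normalization and -0.06 with a common median.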

Other observations

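Called genes often lay beside each other in the genome. The adenylate kinase gene Ak4 and its neighbour Dnajc6, which encodes the clathrin uncoating factor auxilin, rose by 4.90 ± 0.34 and 4.81 ± 0.30 (SE, n = 3 per group). The interleukin 25 receptor subunit Il17rb and the choline dehydrogenase Chdh rose by 5.37 ± 0.22 and 3.51 ± 0.19, and Gca stands beside Ifih1, which rose by 3.06. Members of gene families also moved together: Chil4, a near-identical relative of Chil3 whose probes could see the same transcripts, rose by 5.41 ± 0.50 (6.02 without WT replicate 3), and Cd200r4 fell by 3.51 ± 0.17 beside Cd200r3. Of these, Ak4, Dnajc6, Il17rb, Chdh, Chil4 and Cd200r4 were chosen after their values were seen. Ak4, Dnajc6 and Chil4 rose from WT means near background (4.76, 4.85 and 4.58), so their sizes are compressed estimates. Over the 16281 pairs of neighbouring genes, with pairs that share the first 3 letters of their symbols and the Y chromosome left out, 129 pairs were called in the same direction and 44 in opposite directions. A permutation test with 1000 reshuffles of the calls among genes of similar level gave 42 to 91 same-direction pairs (mean 66.3, one-sided p = 0.001, the smallest the reshuffles can give). Related genes with unlike symbols, such as Prtn3 and Elane, remain among the 129 pairs. Without pairs that hold a gene with a 3-letter relative within 5 places, a filter chosen after the result was seen, 102 pairs of 13302, Prtn3 and Elane still among them, were called in the same direction against 36 to 80 in reshuffles. Shared regulation of neighbours may add to this excess, and so may local differences in DNA between lines of different origin, which were not tested.

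The tests of the loss of the Y chromosome, of K313 RNA in WT replicate 3 and of the basophil and mast cell genes, with the selection repeated for each WT array, were chosen after the result was seen; the X-linked escape, WT-high, neighbour and split tests were set before their result was seen.

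The first pattern is the Y-linked difference. Kdm5d, Uty and Eif2s3y rose by 4.63, 7.23 and 7.88 in K313. If the WT line carried 2 X chromosomes, genes that escape X inactivation should be lower in K313. Their median change over 6 genes was -0.52 (mean -0.47 ± 0.08, SE over arrays). Past the threshold were 3 of 6, Kdm6a (-1.09 ± 0.24), Kdm5c (-0.95 ± 0.15) and Pbdc1 (-0.70 ± 0.15). The other 3 did not pass, and 2 of them were not lower: Ddx3x differed by 0.19 ± 0.16, Utp14a by 0.07 ± 0.16 and Eif2s3x by -0.34 ± 0.17. Kdm6a missed the threshold without WT replicate 2 (adjusted p = 0.0549), WT replicate 3 (0.0633), K313 replicate 2 (0.0598) or K313 replicate 3 (0.0733). Pbdc1 missed it without K313 replicate 2 (0.0647) or K313 replicate 3 (0.0562), so that 1 to 3 of 6 passed with 1 array left out, while the median ran from -0.59 to -0.47. The median of the full fit lay at the 0.32 percentile of 10000 random sets of X-linked genes of similar level, which argues against the loss of the Y chromosome from WT cells with 1 X chromosome. Although not all 6 genes follow, the values are consistent with WT cells from a female and K313 cells from a male animal, so that any difference between the groups may hold differences of sex and line besides those of the C/EBPα form, which this design cannot part.

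The second pattern is WT replicate 3. In 49 genes high in K313 and low in WT replicates 1 and 2, with limits on level and change chosen after a first look, this array held a median of 3.05% of the K313 level (middle 50% of genes 1.83% to 4.34%) and lay above both other WT arrays in 40 of 49. These genes were picked as low in the other 2 WT arrays, which favours such a count. The same selection made with WT replicate 1 or 2 as the array left out gave 7 of 29 and 2 of 35, with median shares of -0.42% and -1.17%. Those selections hold WT replicate 3 among the other WT arrays, which by itself lowers the counts and shares. Taken over the lower of the other 2 WT arrays, the median shares were 0.086% for WT replicate 1, -0.015% for WT replicate 2 and 3.75% for WT replicate 3. The 3 Y-linked genes held 2.54% (2.37% to 3.40%), inside the middle 50% of those 49 genes, which cells without a Y chromosome would not make. A small share of RNA or cells of the K313 line in this sample is a candidate explanation. If these cells were instead further along towards the K313 state, genes high in WT should be lower there; their median difference in 86 such genes was -0.14, above the bound of -0.3 set beforehand. The same measure was 0.185 for WT replicate 1 and -0.055 for WT replicate 2, so that WT replicate 3 was the lowest. Each value sets 1 array against the mean of the others, so the values depend on each other and give no separate measure of spread. A carried-over share of the median size would by itself lower these genes by 0.045. The quartiles, -0.49 and 0.12, span the bound of -0.3, and the requirement that they clear it was added after the value was seen. A partial shift in the cells of WT replicate 3 therefore stays open beside carried-over K313 RNA, which remains a candidate.

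The third pattern is the fall of basophil and mast cell genes. If only such cells expressed these genes, a smaller share would lower them alike. The changes of the 12 members above a WT level of 6 had an SD of 2.10 (1.35 without Prss34), with 9 lower and Prss34 higher. Genes of this list such as Gata2 are also expressed in progenitors, so unequal falls cannot decide whether the share was smaller. A smaller share would not by itself raise Prss34, but that is 1 member, and the test was chosen after its rise was seen. A smaller share therefore stays open. A difference between lines of different animals may give the same values and cannot be told apart from the genotype, since each genotype came with its own Y-linked pattern (3 Y-linked genes past the threshold). An effect of the K313 form on lineage genes stays among the open explanations.

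The real split of the 6 arrays gave 1720 probe sets and the highest of the other splits 0 with limma (499 to 1088 at an unadjusted p under 0.05, 0 with ordinary variance). As large a count came from 1 of the 10 splits, the real one, and 10 splits are too few for a share under 0.05.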
